A study of Rattus norvegicus with 10 samples.

How the data were processed

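RNA from 10 cultures of neonatal rat ventricular cells was sequenced, per the labels, as TruSeq libraries multiplexed on 1 lane. Per the submitters' processing notes, reads were trimmed with cutadapt (no version given), aligned with TopHat2 2.0.10 to the rat genome build Rnor_6.0, counted per gene with HTSeq 0.6.1p1 and compared with DESeq2 1.6.3; the annotation release and the strand setting are not stated. The deposited table gives a read count per gene symbol and library, in whole numbers without normalization. The authors' deposited table also gives, per the file headers, a log2 fold change for each of their 4 comparisons, and an adjusted p-value for each, from DESeq2. Its 10 columns of further per-library values were not used here. Counts exist for symbols alone, without positions, so none are printed; 19092 of the 28522 symbols matched current rat gene names.

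Library totals ran from 18048944 to 22794744 counts, and 19808 symbols had a count in any library. Floors and counting intervals cover counting error only, and ratios to 1 to 3 counts have an exact binomial interval. Counts were scaled by the trimmed mean of M values and filtered with filterByExpr (minimum count 10, minimum total 15), which left 13869 genes. A quasi-likelihood model with robust dispersion was fitted to all 10 libraries with edgeR 4.0.16 in R 4.3.3, with 1 coefficient per group. The 5 contrasts were cell type in serum-free medium, cell type with phenylephrine, phenylephrine in cardiomyocytes, phenylephrine in fibroblasts, and the difference between the last pair. All tests were two-sided unless stated, and a gene was called at a Benjamini-Hochberg adjusted p below 0.05 within its contrast. Log2 values are fitted fold changes, and ± gives their standard error unless SD is stated.

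Gene lists were tested with camera from limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation of 0.01, with adjustment over the lists within each contrast and with at least 5 members. Camera was repeated with a correlation estimated per list. The 31 lists, with 631 entries of which 592 were tested, covered the sarcomere, calcium handling and excitation, the hypertrophy program, immediate early and AP-1 genes, cardiac and fibroblast transcription factors, the extracellular matrix, fibroblast surface markers, myofibroblast genes, actin and SRF targets, TEAD and YAP targets, TGF-beta targets, fatty acid oxidation, oxidative phosphorylation, the citrate cycle, glycolysis, the cell cycle, adrenergic receptors, Gq signalling, ribosome biogenesis, amino acid synthesis and ATF4 targets, the unfolded protein response, cholesterol synthesis, inflammation, interferon response, and markers of endothelial, leukocyte, smooth muscle and pericyte, epicardial, Schwann and neural, and erythroid cells. Groups, contrasts, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule named, per contrast, the 6 genes with the largest rise and the 6 with the largest fall among those called, with at least 10 CPM in the higher group and no overlap between the libraries of the groups, leaving out provisional gene names. It also named a fixed panel of 24 genes and, per described list, up to 4 members of smallest adjusted p. Genes named outside the rule are said to be so. Genes that overlap a neighbour or have a near copy can share reads, and the strand setting is unknown, so single values of Tnni3k, B3galt2, Col1a1, Timp1, Eno3, Cxcl10, Nt5e, Idi1, Ptx3, Tead2, Cspg4, Ifit1, Zeb2, Pde3b and Pla2g2a carry this limit.

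The tests were run on simulated data with the measured depths and the trend of the dispersion over all genes. Genes were drawn independently and no library stood apart, unlike in the real data. The results therefore do not give the power or the false calls, of genes or of lists, in the real comparisons. At a true fold of 1.5, 2 and 4, edgeR called 94%, 100% and 100% of changed genes for phenylephrine in cardiomyocytes, 91%, 97% and 100% in fibroblasts, and 31.3%, 85.1% and 97% for the difference between cell types, with 7, 11 and 6 unchanged genes called. For cell type it called 76.1%, 97% and 100% in serum-free medium and 82.1%, 95.5% and 100% with phenylephrine. A list shifted by 1.5-fold was called by camera in every contrast, and at most 1 other list was called. The alternatives were relative log expression factors, DESeq2 1.42.0, limma-voom, no filter, a filter at 10 CPM, a fold of at least 2, a fit of the compared groups alone, a replicate block, and leaving out each library in turn. Scaling by library size alone, leaving out both libraries that stand apart, a surrogate variable (sva 3.50.0), a block with the fibroblast numbers crossed, and repeating the lists without each library were chosen after seeing the data.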

Results

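Gene expression was measured by RNA sequencing in primary cultures of neonatal rat ventricular cardiomyocytes, the contractile cells of the heart, and of cardiac fibroblasts, the connective tissue cells that make its extracellular matrix. Both were prepared from the hearts of newborn rats by enzymatic digestion and separated on a Percoll density gradient. At 24 h after plating the medium was replaced by serum-free medium, with or without 10 µM phenylephrine, an agonist of alpha1-adrenergic receptors that is widely used to provoke hypertrophic growth of cultured cardiomyocytes. The 10 libraries formed 4 groups: cardiomyocytes in serum-free medium (n = 3), cardiomyocytes with phenylephrine (n = 3), fibroblasts in serum-free medium (n = 2) and fibroblasts with phenylephrine (n = 2). Cardiomyocytes were not passaged and fibroblasts were at passage 2, so cell type and passage could not be separated. The labels give neither the time in phenylephrine nor whether replicates were separate cultures or animals, so every p-value measures the spread between these libraries and no more.

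Total counts were 19774387, 18737317 and 22794744 in the serum-free cardiomyocyte libraries and 19337032, 18397495 and 20908662 in those with phenylephrine. In fibroblasts they were 20217665 and 19715598 in serum-free medium and 19192379 and 18048944 with phenylephrine. A floor of 3 counts corresponded to between 0.132 and 0.166 CPM (counts relative to library size) in these libraries, counting error alone. The mitochondrially encoded genes took 6.49% to 7.5% of the counts in cardiomyocytes and 2.7% to 3.26% in fibroblasts. Principal component 1 held 90.1% of the variance and separated the cell types. Replicates differed by 2.42 to 22.6 times the counting variance (chi-square per degree of freedom). In cardiomyocytes, the library with phenylephrine replicate 1 differed from its group mates by 18.3 and 22.6 against 2.99 between those mates, and serum-free replicate 2 by 21.9 and 22.6 against 4.2. These 2 libraries are described beside the results they bear on.

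The comparison of the 2 cell types in serum-free medium (3 against 2 libraries) asked how their transcriptomes differ without agonist. Nppa and Nppb, the natriuretic peptides secreted by heart muscle cells, were 774-fold and 1110-fold higher in cardiomyocytes, at log2 9.60 ± 0.18 and 10.12 ± 0.14 (SE). The cardiac myosin heavy chains Myh6 and Myh7 were 893-fold and 757-fold higher, and Nkx2-5, a transcription factor of the cardiac lineage, was 289-fold higher. Extracellular matrix transcripts lay the other way: Col11a1, a minor fibrillar collagen, was 62.9-fold lower in cardiomyocytes (log2 -5.97 ± 0.46), Eln, which encodes elastin, 48.7-fold lower, Col1a1 5.5-fold lower and Postn, the matricellular protein periostin, 3.96-fold lower. Tnni3k, a kinase named for its binding to troponin I, had no count in either serum-free fibroblast library and was at least 817-fold higher in cardiomyocytes, taking a floor of 3 counts over the group. By the same floor Kcnj11, the pore-forming subunit of ATP-sensitive potassium channels, was at least 356-fold higher, Tecrl at least 291-fold, Ptgds, a prostaglandin D synthase, at least 287-fold, B3galt2 at least 236-fold and Slc39a2, a zinc transporter, at least 180-fold. Besides Col11a1 and Eln, the largest differences in favour of fibroblasts were Ighm, the immunoglobulin mu heavy chain, at log2 -7.94 ± 0.36, Dpp6 at -6.69 ± 0.26, Grik2, a kainate receptor subunit, at -5.82 ± 0.34 and Myh2, a skeletal muscle myosin, at -5.69 ± 0.29. In all, 9169 of 13869 genes differed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05), 4779 higher and 4390 lower in cardiomyocytes, and 3972 of them by at least 2-fold.

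Transcription factors shared by both lineages differed less. Gata4 was 1.8-fold higher in cardiomyocytes (log2 0.85 ± 0.065) and Mef2c 1.47-fold (0.56 ± 0.12), whereas Tbx5 was 17.4-fold higher. Tcf21, a marker of the fibroblast lineage, was 3.76-fold lower, and Twist1 1.34-fold lower. The Twist1 call (edgeR adjusted p = 0.019) was lost without serum-free cardiomyocyte replicate 3 or serum-free fibroblast replicate 1. Tead1, the nuclear partner of YAP, did not pass the test (log2 -0.17 ± 0.085, edgeR adjusted p = 0.107), nor did Myc (0.44 ± 0.18, adjusted p = 0.0503). Of the list of cardiac transcription factors, 22 of 25 measured genes were higher and 1 lower, in the same numbers when adjusted over the list alone, among them Esrrg (log2 7.66), Myocd (5.59), Prox1 (5.96) and Smyd1, with a ratio of 2080 (95% counting interval 712 to 10100) to 3 counts over the fibroblast group. Of the fibroblast transcription factors, 20 of 23 were lower and 1 higher (20 and 1 adjusted over the list alone), with Osr1 at log2 -3.42, Sox9 at -3.02 and Zeb2 at -1.29. Camera, which ranks a list against all other genes, placed the cardiac factors higher (adjusted p = 4.29e-07) and the fibroblast factors lower (3.41e-05); these become adjusted p = 0.176 and 0.355 with an estimated correlation.

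Contractile, electrical and energy genes were among the higher lists in cardiomyocytes. All 28 measured sarcomere genes were higher (28 adjusted over the list alone), with a median log2 difference of 8.66, led by Myl2 (11.04 ± 0.18), Tnni1 (10.22 ± 0.15) and Myoz2 (8.21 ± 0.12). Of the calcium handling and excitation genes, 20 of 22 were higher and 1 lower (20 and 1 adjusted over the list alone), including the ryanodine receptor Ryr2 (9.31 ± 0.18). The hypertrophy list had 17 of 24 genes higher and 5 lower, with the same counts adjusted over the list alone. Every one of 23 oxidative phosphorylation genes and 15 citrate cycle genes was higher (23 and 15 adjusted over the list alone), as were 23 of 25 fatty acid oxidation genes (23) and 20 of 22 glycolysis genes (20, with 2 lower). Examples are the fatty acid transporter Cd36 (7.49 ± 0.17), Acadm (2.28 ± 0.069), Cox6a2, the muscle isoform of a cytochrome oxidase subunit (8.68 ± 0.17), and the insulin-regulated glucose transporter Slc2a4 (5.80 ± 0.16). Camera adjusted p was 5.27e-17 for the sarcomere, 5.1e-09 for calcium and excitation, 0.000342 for hypertrophy, 2.78e-11 for oxidative phosphorylation, 1.28e-07 for the citrate cycle, 9.14e-08 for fatty acid oxidation and 1.95e-05 for glycolysis. In that order the lists had adjusted p = 0.19, 0.149, 0.227, 0.341, 0.355, 0.221 and 0.355 with an estimated correlation. Hba and Hbb, Myh6 and Myh7, and Acta1, Actc1 and Acta2 are near copies whose reads the counting could split, so single values of these genes are uncertain.

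Matrix, growth and biosynthetic lists were lower in cardiomyocytes. Of 30 extracellular matrix genes, 26 were lower and 1 higher (26 and 1 adjusted over the list alone), with Fn1, fibronectin, at log2 -2.21 ± 0.11 and Sparc at -1.47 ± 0.13. Myofibroblast genes were lower for 12 of 16 and higher for 1 (13 and 1 adjusted over the list alone), fibroblast surface markers for 9 of 12 and 2 (9 and 2), TGF-beta targets for 15 of 20 and 2 (15 and 2), TEAD and YAP targets for 15 of 19 and 4 (15 and 4), and actin and SRF targets for 14 of 23 and 6 (15 and 6). Cholesterol synthesis genes were lower for 18 of 21 (18 adjusted over the list alone), with Lss at -1.57 ± 0.075, Nsdhl at -1.55 ± 0.086 and Insig1, a brake on sterol synthesis, at -1.6 ± 0.098. Amino acid synthesis and ATF4 targets were lower for 16 of 20 and higher for 1 (17 and 1 adjusted over the list alone), such as Phgdh, which opens serine synthesis, at -1.45 ± 0.085. Unfolded protein response genes were lower for 9 of 18 and higher for 2, and ribosome biogenesis genes lower for 11 of 22 and higher for 1, both unchanged when adjusted over the list alone. Camera adjusted p was 4.29e-07 for the matrix, 0.000562 for myofibroblast genes, 0.0293 for fibroblast surface, 0.00148 for TGF-beta, 0.00249 for TEAD and YAP, 0.0268 for actin and SRF, 1.81e-06 for cholesterol, 3.67e-05 for amino acid synthesis, 0.0199 for the unfolded protein response and 0.0292 for ribosome biogenesis. None held with an estimated correlation, the lowest being adjusted p = 0.355 with an estimated correlation and the highest 0.637. Without the 2 cardiomyocyte libraries that stand apart, an alternative chosen after seeing the data, ribosome biogenesis (adjusted p = 0.074) and the unfolded protein response (0.0609) lost their calls with the preset correlation too. Without serum-free cardiomyocyte replicate 2 alone they had adjusted p = 0.0668 and 0.0765, and without serum-free fibroblast replicate 1 both had 0.0721. Cell cycle genes showed no shift (camera adjusted p = 0.968), with 2 of 29 higher and 1 lower (0 adjusted over the list alone). Immediate early and AP-1 genes went both ways, 5 of 20 higher and 9 lower (7 and 9 adjusted over the list alone, camera adjusted p = 0.559). The median of the cell cycle list was 0.08 and that of the immediate early list 0.04, both positive, where camera pointed lower; the mean of the latter was -0.15.

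Adrenergic receptor transcripts differed strongly between the cell types. Adra1a, an alpha1 receptor and a target of phenylephrine, was at 18.1 ± 1.79 CPM (SD, n = 3) in serum-free cardiomyocytes and 0.0759 ± 0.107 CPM (n = 2) in fibroblasts, a ratio of 236 (95% counting interval 80.4 to 1140; edgeR adjusted p = 2.54e-09). Adra1b was 30.8-fold higher in cardiomyocytes, at 11.2 CPM against 0.357 CPM, and Adra1d had a ratio of 39.4 (13.3 to 193), at 3.03 CPM against 0.0774 CPM. Adra1a and Adra1d each had 3 counts over the fibroblast group. The beta1 receptor Adrb1 was 6.26-fold higher. Of 7 measured adrenergic receptors 5 were higher in cardiomyocytes and 2 lower, in the same numbers when adjusted over the list alone (camera adjusted p = 0.139). Genes of Gq signalling, the pathway downstream of alpha1 receptors, went both ways, 7 of 22 higher and 9 lower (7 and 9 adjusted over the list alone, camera adjusted p = 0.734), with Dusp5 at log2 4.78 ± 0.25 and Plcb3 at -1.78 ± 0.064.

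Markers of other cell types and inflammatory genes were also higher in the cardiomyocyte cultures. All 17 measured leukocyte markers were higher (17 adjusted over the list alone), with Lyz2 at 33.6 CPM against 2.12 CPM, Fcer1g at log2 3.36 ± 0.19 and Ptprc at 2.63 ± 0.21. Epicardial markers were higher for 9 of 12 and lower for 2, endothelial markers for 9 of 13 and 3, both the same adjusted over the list alone, with Msln, a mesothelial protein, at 57.6 CPM against 1.2 CPM and Kdr, a VEGF receptor, at 13.7 CPM against 0.129 CPM. Interferon-stimulated genes were higher for 18 of 20 and lower for 1, and inflammation genes for 13 of 17 and 3, again the same adjusted over the list alone, with Isg15 at log2 5.17 ± 0.29 and Cxcl10 at 6.65 ± 0.56. Camera adjusted p was 1.81e-06 for leukocyte, 0.0142 for epicardial and 0.0393 for endothelial markers, 5.7e-06 for interferon and 0.0393 for inflammation. The 5 lists had adjusted p = 0.355, 0.396, 0.482, 0.355 and 0.585 with an estimated correlation. The endothelial call was lost without serum-free cardiomyocyte replicate 2 (camera adjusted p = 0.0857) and without both libraries that stand apart (0.0849). The inflammation call was lost without serum-free cardiomyocyte replicate 1 (0.0543) or serum-free fibroblast replicate 1 (0.0687) or 2 (0.083). No camera call was made for 3 marker lists: smooth muscle and pericyte markers (5 of 14 higher and 8 lower), Schwann and neural markers (2 of 8 and 1) and erythroid markers (3 of 5 and 1), all with the same counts adjusted over the list alone. Dbh, an enzyme of noradrenaline synthesis, was 9.7-fold higher in cardiomyocyte cultures, and Hbb, a globin, at least 133-fold.

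With phenylephrine (3 against 2 libraries, none shared with the serum-free comparison) the same contrast of cell types was measured again. Nppb (log2 9.96 ± 0.14), Nppa (9.44 ± 0.18), Myh7 (9.57 ± 0.21) and Ryr2 (8.85 ± 0.18) were again higher in cardiomyocytes, and Col11a1 (-5.51 ± 0.45), Fn1 (-1.53 ± 0.11) and Tcf21 (-2.74 ± 0.17) lower. The largest differences included Inpp5j, an inositol phosphatase, at least 793-fold higher, Nsg2 at least 373-fold, Kcnj11 at least 296-fold and Tcap, the titin cap of the Z-disc, at least 168-fold, beside Xirp2 (11.52 ± 0.48) and Bmp7, with a ratio of 2750 (95% counting interval 493 to 109000) to 1 count over the fibroblast group. On the other side were Akr1c14 (-6.36 ± 0.29), Cpxm2 (-6.07 ± 0.15), the retinaldehyde dehydrogenase Aldh1a1 (-5.45 ± 0.31), Nppc, the C-type natriuretic peptide (-5.45 ± 0.25), and Dync1i1 (-5.37 ± 0.43). Mef2c was 3.77-fold higher in cardiomyocytes and Adra1b 5.48-fold. In total 9008 genes differed (edgeR, Benjamini-Hochberg), 4674 higher and 4334 lower, of which 3963 and 3592 were called in the same direction in serum-free medium and 23 and 27 in the opposite one. Camera called 21 lists, against 24 in serum-free medium, and 0 in either with an estimated correlation. Cholesterol genes were lower for 12 of 21 and higher for 4 (13 and 5 adjusted over the list alone, camera adjusted p = 0.0303, and adjusted p = 0.652 with an estimated correlation), and the call was lost without cardiomyocyte phenylephrine replicate 1 (0.0583) and without both libraries that stand apart (0.0736). Epicardial markers were called too, but not without that replicate (0.0604). Actin and SRF targets had no call here (0.303). TEAD and YAP targets were called lower without fibroblast phenylephrine replicate 2 (0.0459) or both libraries that stand apart (0.0257), and inflammation genes higher without cardiomyocyte phenylephrine replicate 1 (0.0314) or both (0.00367).

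**Figure D1:**
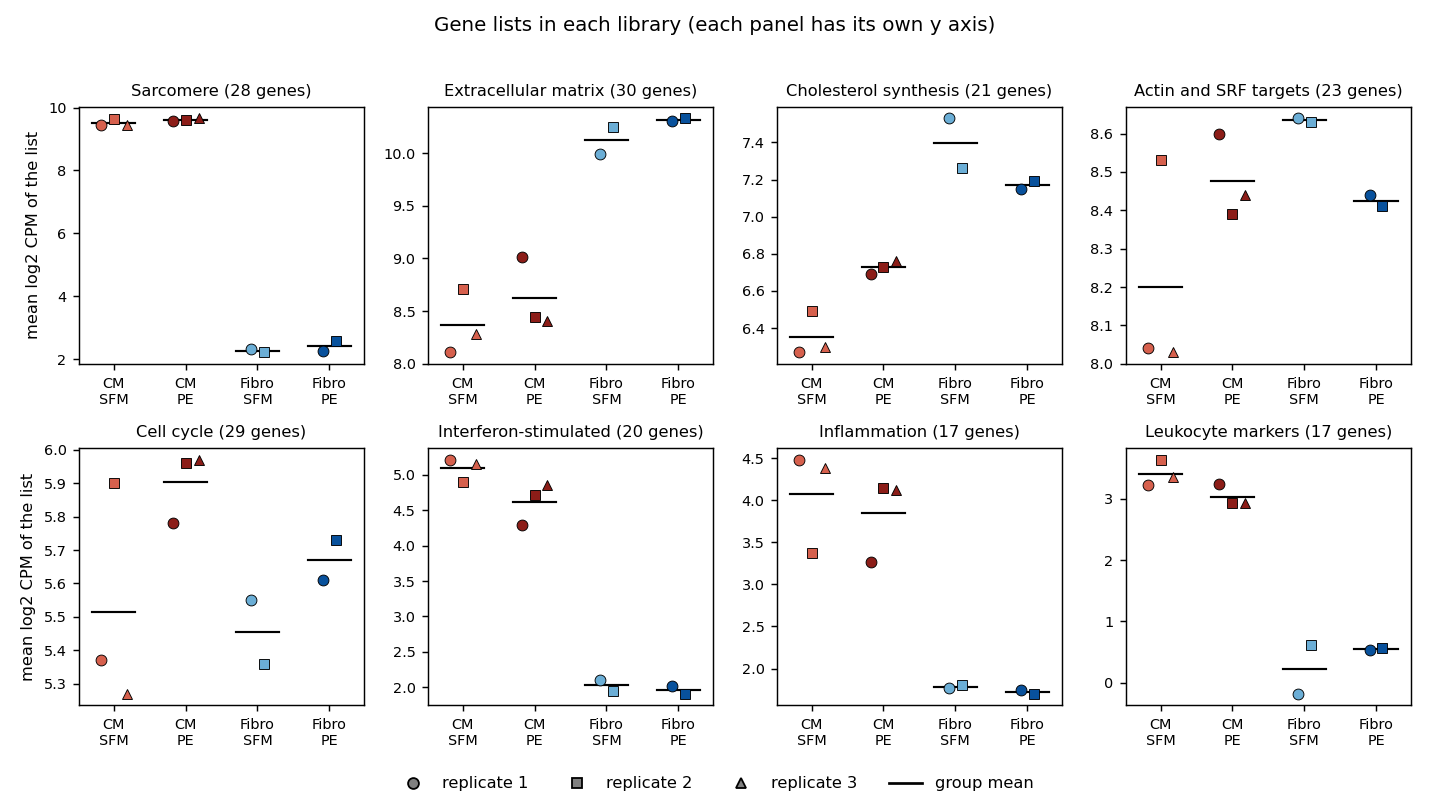
Mean log2 CPM of 8 gene lists in each of the 10 libraries, with cardiomyocytes (CM) and fibroblasts (Fibro) in serum-free medium (SFM) or with phenylephrine (PE) on the x axis; points are libraries, marked by replicate number, and lines are group means. The matrix list stood at 9.01 in cardiomyocyte phenylephrine replicate 1 and 8.71 in serum-free replicate 2, above the other 4 cardiomyocyte libraries, and inflammation at 3.27 and 3.37, below them.

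Phenylephrine in cardiomyocytes (3 against 3 libraries) tests the transcriptional response to an alpha1 agonist in the cultures with more of the receptor transcripts. These cultures also had higher markers of leukocytes, epicardial and endothelial cells than the fibroblasts. Changes within cardiomyocytes cannot be told apart here from changes in the number or state of such cells. Inha, the inhibin alpha subunit, rose by log2 1.84 ± 0.14 (edgeR adjusted p = 0.00115) and the orphan nuclear receptor Nr4a3 by 1.01 ± 0.10. Other large rises were Myl1, a skeletal muscle myosin light chain (1.88 ± 0.34), Hsf2bp (1.71 ± 0.37), Lppr5 (1.47 ± 0.23), Fbn2, a fibrillin of the matrix (1.47 ± 0.31), and the muscle enolase Eno3 (1.25 ± 0.14). Gnb3, a G protein beta subunit (-2.06 ± 0.42), Star, which carries cholesterol into mitochondria (-1.87 ± 0.21), Rac2, a small GTPase of blood cells (-1.58 ± 0.18), the betaine transporter Slc6a12 (-1.51 ± 0.28) and the metallothioneins Mt2A (-1.53 ± 0.31) and Mt1 (-1.45 ± 0.28) fell. The metallothioneins are near copies, which makes their single values uncertain. In all 503 of 13869 genes changed (edgeR, Benjamini-Hochberg), 248 up and 255 down, 89 of them by at least 2-fold. Scaling by library size alone gave 179 up and 396 down.

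Among cholesterol synthesis genes, 11 of 21 rose and none fell (16 and 0 adjusted over the list alone), by a median log2 of 0.44, for example Idi1 (0.72 ± 0.11), Cyp51 (0.54 ± 0.075), Fdft1 (0.54 ± 0.093), which encodes squalene synthase, and Hsd17b7 (0.53 ± 0.083). Camera placed the list higher (adjusted p = 4.48e-10, and adjusted p = 0.468 with an estimated correlation). Interferon-stimulated genes fell for 6 of 20 and rose for none (9 and 0 adjusted over the list alone), including Ifi27 (-0.6 ± 0.067), Bst2 (-0.56 ± 0.11) and Ifit1 (-0.67 ± 0.14), with camera adjusted p = 1.27e-07 (adjusted p = 0.468 with an estimated correlation). TGF-beta targets rose for 6 of 20 (10 up and 1 down adjusted over the list alone), among them the feedback inhibitors Skil (0.38 ± 0.065) and Smad7 (0.43 ± 0.088) and the collagen Col7a1 (1.04 ± 0.24), with camera adjusted p = 7.91e-05 (adjusted p = 0.468 with an estimated correlation). TEAD and YAP targets rose for 3 of 19 (3 up and 1 down adjusted over the list alone), namely Nt5e (0.55 ± 0.088), Dock5 (0.45 ± 0.087) and Ajuba (0.34 ± 0.081), with camera adjusted p = 0.000935 (adjusted p = 0.684 with an estimated correlation). In Gq signalling, Spry4, a feedback inhibitor of ERK signalling, rose (0.42 ± 0.096), 1 of 22 genes (3 adjusted over the list alone), with camera adjusted p = 0.00474 (adjusted p = 0.468 with an estimated correlation).

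Several lists were shifted as a whole while few or none of their genes passed alone. The cell cycle list lay higher by a median log2 of 0.49 with 0 of 29 genes called, actin and SRF targets by 0.28 with 0 of 23, the matrix by 0.40 with 0 of 30 and myofibroblast genes by 0.45 with 1 of 16, Ddah1 (0.62 ± 0.11). Adjusted over the list alone the counts were 0, 0, 0 and 2. Camera adjusted p was 1.86e-05, 0.000438, 0.00597 and 0.000451 in that order, and each had adjusted p = 0.684 with an estimated correlation. In the libraries that stand apart, mean log2 CPM of actin and SRF targets was 8.53 in serum-free replicate 2 against 8.04 and 8.03 in its mates, and 8.6 in phenylephrine replicate 1 against 8.39 and 8.44. Cell cycle genes were at 5.9 in serum-free replicate 2 against 5.37 and 5.27, and at 5.78 in phenylephrine replicate 1 against 5.96 and 5.97. Sarcomere genes were called higher by camera (adjusted p = 0.0186, and adjusted p = 0.684 with an estimated correlation) with 0 of 28 genes called (7 up and 1 down adjusted over the list alone), and smooth muscle and pericyte markers (0.00597, and adjusted p = 0.684 with an estimated correlation) with Cspg4 up (0.91 ± 0.19) and Abcc9 down (-0.55 ± 0.11), or 3 and 1 adjusted over the list alone. The matrix call was lost without phenylephrine replicate 1 (0.485) or serum-free replicate 1 (0.116), the smooth muscle call without the same libraries (0.064 and 0.051), and the sarcomere call without phenylephrine replicate 3 (0.0785) or serum-free replicate 1 (0.115) or 3 (0.0614).

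Other lists lay lower beside interferon. Oxidative phosphorylation genes fell for 2 of 23 (3 adjusted over the list alone), Cox8b (-1.04 ± 0.14) and Ndufb8 (-0.26 ± 0.059), and fatty acid oxidation genes for 1 of 25 (1), Eci1 (-0.28 ± 0.067). Their camera adjusted p was 0.00754 and 0.0157 (each adjusted p = 0.684 with an estimated correlation), and without both libraries that stand apart 0.585 and 0.18. Without phenylephrine replicate 1 it was 0.471 and 0.333, and without serum-free replicate 3 fatty acid oxidation had 0.0668. Sdf2l1 fell in the unfolded protein list, 1 of 18 (1 adjusted over the list alone, camera adjusted p = 0.0157, and adjusted p = 0.684 with an estimated correlation). Leukocyte markers fell for 3 of 17 (8 adjusted over the list alone), Laptm5 (-0.78 ± 0.16), Ptprc (-0.62 ± 0.15) and Fcer1g (-0.59 ± 0.13), with camera adjusted p = 0.00286 (adjusted p = 0.684 with an estimated correlation, and 0.0699 without both libraries). Of the erythroid markers Hba-a2 fell (-2.18 ± 0.45), 1 of 5 (2 adjusted over the list alone, camera adjusted p = 0.0186, and adjusted p = 0.468 with an estimated correlation). The unfolded protein call was lost without phenylephrine replicate 3 (0.0798) or serum-free replicate 1 (0.126) or 3 (0.0728), and the leukocyte and erythroid calls without serum-free replicate 2 (0.124 and 0.0513). Inflammation genes showed no call (camera adjusted p = 0.228, 0 of 17 changed, 2 down adjusted over the list alone), but were called lower without serum-free replicate 2 (0.00379) and without both libraries that stand apart (0.00993). Their mean log2 CPM was 3.27 in phenylephrine replicate 1 and 3.37 in serum-free replicate 2, against 4.12 to 4.48 in the other cardiomyocyte libraries.

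With all 6 libraries, 5 classical hypertrophy markers did not pass the test. Nppa changed by log2 0.17 ± 0.10 (edgeR adjusted p = 0.343), Nppb by 0.09 ± 0.073 (0.499), Acta1 by 0.45 ± 0.25 (0.338), Ankrd1 by 0.15 ± 0.13 (0.53) and Myh7 by 0.45 ± 0.12 (0.0558). This depended on the 2 libraries that stand apart: without both, Acta1 rose by 0.90 ± 0.062 (edgeR adjusted p = 1.05e-08) and Myh7 by 0.62 ± 0.074 (7.53e-06), and Nppa, Nppb and Ankrd1 did not pass (0.0934, 0.0962 and 0.344). Of 24 genes in the hypertrophy list, Timp1 (0.55 ± 0.088) and Tnfrsf12a (0.30 ± 0.074) rose and Fgf16 (-0.77 ± 0.17) and Rcan1, a calcineurin target (-0.43 ± 0.093), fell, or 3 and 3 adjusted over the list alone (camera adjusted p = 0.083, and called higher at 0.0148 without serum-free replicate 2). Among cardiac transcription factors Mef2c (0.56 ± 0.10), Tbx20 (0.44 ± 0.11) and Gata4 (0.23 ± 0.056) rose and Hopx (-1.29 ± 0.16) fell, 3 and 1 of 25 (4 and 2 adjusted over the list alone, camera adjusted p = 0.283). Adra1b fell by 0.79 ± 0.19 on the log2 scale (edgeR adjusted p = 0.0481), 1 of 7 receptors (1 up and 1 down adjusted over the list alone), while Adra1a had 0.46 ± 0.12 (0.0647). Besides Nr4a3, Ier3 rose (0.34 ± 0.048) among the immediate early genes, 2 of 20 (3 up and 1 down adjusted over the list alone, camera adjusted p = 0.404).

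These calls depended on single libraries. Without phenylephrine replicate 1 the test called 1084 genes and without serum-free replicate 2 it called 2371, whereas without phenylephrine replicate 2 or 3 or serum-free replicate 1 or 3 it called 32, 51, 43 and 48. Inha, Nr4a3, Cyp51, Eno3, Ifi27, Rac2 and Star kept their calls in each of these 6 settings, and every other gene named as changed here lost its call in at least 1. Without both libraries that stand apart, an alternative chosen after seeing the data, 3486 genes changed (1820 up and 1666 down), which included 501 of the 503 in the same direction. In that fit Acta2 rose by log2 1.06 ± 0.072 and Col1a1 by 0.53 ± 0.076, and the hypertrophy list was called higher (camera adjusted p = 0.0291). Lists without a call in all 6 libraries gained one in other settings: glycolysis, higher without phenylephrine replicate 1 (0.0156) or both libraries that stand apart (0.0109), epicardial markers, lower without the same (0.0156 and 0.0166), amino acid synthesis and ATF4 targets, lower without serum-free replicate 2 (0.00678) or both (0.00476), and fibroblast transcription factors, higher without phenylephrine replicate 2 (0.00897) or serum-free replicate 2 (0.0131). With all 6 these lists had camera adjusted p = 0.526, 0.191, 0.115 and 0.102.

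In fibroblasts phenylephrine was compared with serum-free medium in 2 against 2 libraries. Cpxm2 rose by log2 3.05 ± 0.14, the prostaglandin transporter Slco2a1 by 2.99 ± 0.22, the cyclin-dependent kinase inhibitor Cdkn1c by 2.86 ± 0.19, the cAMP phosphodiesterase Pde4b by 2.83 ± 0.11 (edgeR adjusted p = 2.19e-07) and Inha by 2.55 ± 0.24. Ighm fell by 2.21 ± 0.25, Slc35f1 by 1.31 ± 0.25, Adprhl1 by 1.22 ± 0.19, Sorbs2 by 1.19 ± 0.15 and the matrix protein tenascin, Tnc, by 1.17 ± 0.18. Nr4a3 (1.75 ± 0.14) and Nr4a1 (1.41 ± 0.19) rose, 2 of 20 immediate early genes (2 up and 2 down adjusted over the list alone, camera adjusted p = 0.877). The test called 531 genes (edgeR, Benjamini-Hochberg), 286 up and 245 down, 150 of them by at least 2-fold. Scaling by library size alone gave 370 up and 184 down.

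Pi16, a marker of quiescent adventitial fibroblasts, rose by log2 2.28 ± 0.24 and Dpep1 by 0.60 ± 0.14, 2 of 12 surface markers (4 up and 1 down adjusted over the list alone, camera adjusted p = 0.0972). Of 23 fibroblast transcription factors Twist2 (1.01 ± 0.25), Tcf21 (0.79 ± 0.18) and Tead2 (0.49 ± 0.087) rose and Osr1 (-0.79 ± 0.16) fell, 3 and 1 also when adjusted over the list alone, with camera adjusted p = 0.0437 (adjusted p = 0.962 with an estimated correlation). With the replicate block this list lost its call (camera adjusted p = 0.0686). TEAD and YAP targets fell for 3 of 19 (7 adjusted over the list alone), Ankrd1 (-0.71 ± 0.16), Tgfb2 (-0.68 ± 0.10) and Lats2 (-0.45 ± 0.073), and among 23 actin and SRF targets vinculin, Vcl, fell (-0.54 ± 0.12), 1 also when adjusted over the list alone. Both lists had camera adjusted p = 0.0185 and adjusted p = 0.962 with an estimated correlation. Cholesterol synthesis genes lay lower by a median log2 of -0.26, with Sc5d called (-0.51 ± 0.11), 1 of 21 (11 adjusted over the list alone), at camera adjusted p = 0.00222 (adjusted p = 0.962 with an estimated correlation). The cell cycle list lay higher with 0 of 29 genes called (0 adjusted over the list alone), at camera adjusted p = 0.0185 (adjusted p = 0.962 with an estimated correlation).

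Of 20 TGF-beta targets 4 rose and 1 fell (9 and 2 adjusted over the list alone, camera adjusted p = 0.0811), with Id1 (1.31 ± 0.21), Id2 (0.68 ± 0.14) and the pseudoreceptor Bambi (0.58 ± 0.12) among those that rose. Tnc and Fn1 (-0.53 ± 0.12) fell among 30 matrix genes (2 adjusted over the list alone, camera adjusted p = 0.324), and Ddah1 (-0.61 ± 0.14) fell with them among 16 myofibroblast genes, 3 in all (4 adjusted over the list alone, camera adjusted p = 0.0972). Mef2c fell by 0.80 ± 0.13 and Gata4 rose by 0.31 ± 0.07. Of 7 adrenergic receptors 1 rose (2 adjusted over the list alone), with a median log2 of 0.52 and camera adjusted p = 0.146, and the list was called higher without phenylephrine replicate 2 (0.0326) or serum-free replicate 1 (0.0464). Adra1b did not pass (1.70 ± 0.51, edgeR adjusted p = 0.0947). In Gq signalling Rgs2 rose (0.63 ± 0.13) and Spry4 fell (-0.76 ± 0.12), 1 and 1 of 22 (2 and 2 adjusted over the list alone). Among inflammation genes the pentraxin Ptx3 rose (0.89 ± 0.11) and Ptgs2, the inducible cyclooxygenase, fell (-0.92 ± 0.15), 1 and 1 of 17, also when adjusted over the list alone (camera adjusted p = 0.93, with a median of 0.14 and a mean of -0.14). Changes for the sarcomere (1 up and 1 down of 28), interferon (1 up of 20) and endothelial (1 and 1 of 13) lists had no camera call, and 4 and 3, 1 and 1, and 1 and 3 genes passed when adjusted over the list alone.

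Leaving out 1 fibroblast library leaves a single sample in that group, which is then assumed to vary like the others. Without phenylephrine replicate 1 or 2 or serum-free replicate 1 the test called 112, 129 and 162 genes, and without serum-free replicate 2 it called 516. Cpxm2, Slco2a1, Cdkn1c, Pde4b, Inha, Ighm, Sorbs2, Nr4a3, Nr4a1, Pi16 and Ptx3 kept their calls in all 4 such settings, and every other gene named as changed here lost its call in at least 1. The cholesterol list lost its camera call without serum-free replicate 1 (adjusted p = 0.118), and the transcription factor list without that library (0.372) or phenylephrine replicate 1 (0.0885) or 2 (0.0751). The TEAD and YAP list lost its call without serum-free replicate 1 (0.0688) or phenylephrine replicate 2 (0.0751), the actin list without serum-free replicate 2 (0.0502) or phenylephrine replicate 2 (0.0751), and the cell cycle list without the same libraries (0.392 and 0.181). Myofibroblast genes were called lower without serum-free replicate 1 (0.0464) and sarcomere genes higher without phenylephrine replicate 1 (0.00129). Without serum-free replicate 2 the unfolded protein list was called lower (0.00309, against 0.0546 with all 4 libraries) and leukocyte markers higher (8.29e-05, against 0.157). The serum-free fibroblast libraries differed by 14.7 times the counting variance and those with phenylephrine by 2.42.

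**Figure D2:**
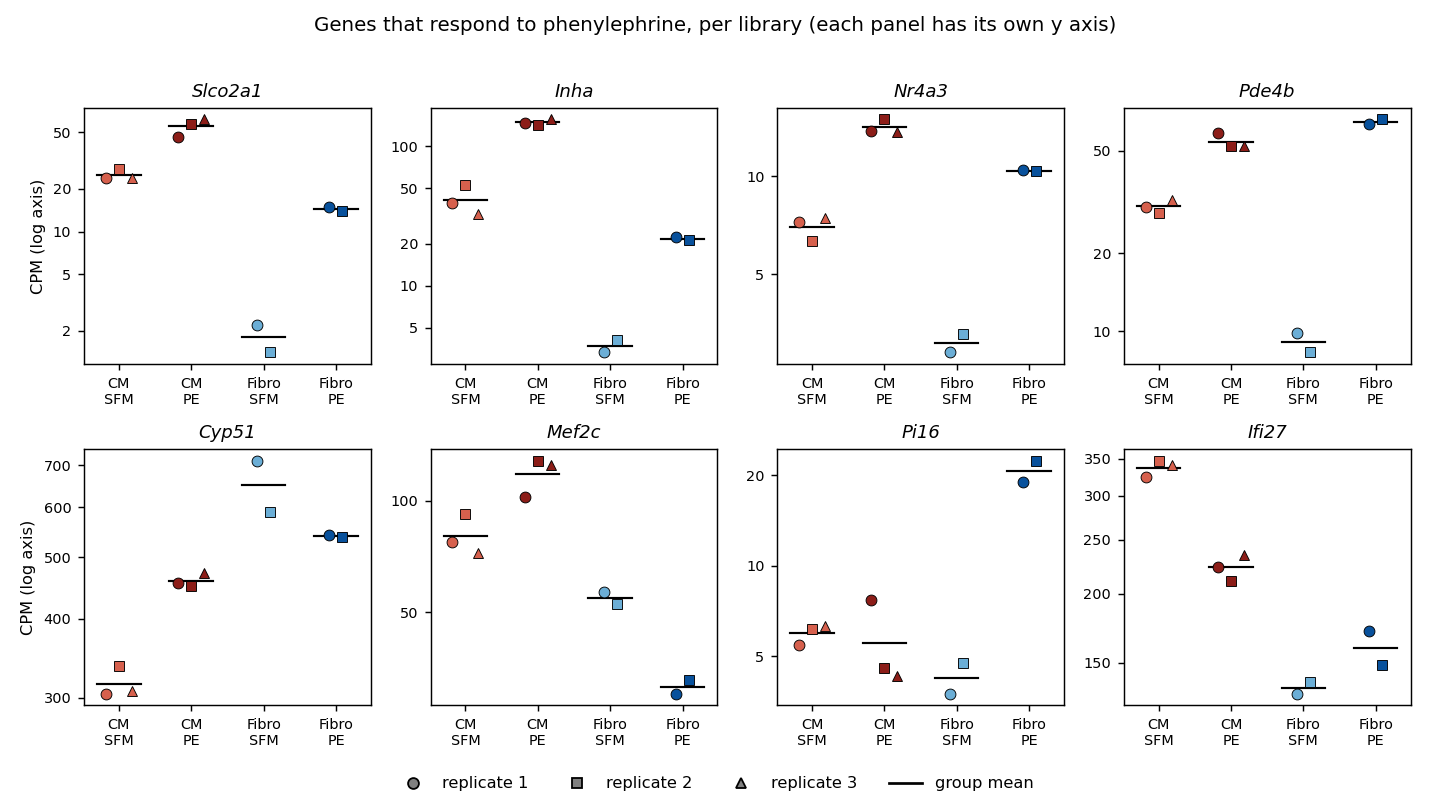
CPM of 8 genes in each library on logarithmic axes, with cardiomyocytes (CM) and fibroblasts (Fibro) in serum-free medium (SFM) or with phenylephrine (PE); points are libraries, marked by replicate number, and lines are group means. Slco2a1, Inha, Nr4a3 and Pde4b rose in both cell types, whereas Cyp51, Mef2c and Ifi27 changed in cardiomyocytes and Pi16 and Mef2c in fibroblasts.

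The responses of the 2 cell types were compared by the interaction, the log2 change in cardiomyocytes minus that in fibroblasts. Mef2c, a transcription factor of muscle differentiation, rose in cardiomyocytes and fell in fibroblasts, a difference of 1.36 ± 0.17 (edgeR adjusted p = 0.00392). Spry4 (1.17 ± 0.16), Tnfrsf12a (0.87 ± 0.12) and Ddah1 (1.23 ± 0.18) also had opposite changes that each passed in both cell types. Other large positive differences were Atcay (1.95 ± 0.37), Fam174b (1.92 ± 0.35), Snap91 (1.90 ± 0.25), Rgs6 (1.6 ± 0.25), Fras1 (1.58 ± 0.32) and Sorbs2 (1.58 ± 0.19). The largest negative ones were Dact2, a modulator of Wnt and TGF-beta signalling (-4.07 ± 0.49), Cdkn1c (-3.35 ± 0.26), Gpd1 (-2.94 ± 0.59), the proteoglycan decorin, Dcn (-2.69 ± 0.57), Adra1b (-2.49 ± 0.54) and Smoc2 (-2.48 ± 0.39). In all 451 genes differed (edgeR, Benjamini-Hochberg), 226 with a positive and 225 with a negative difference, 157 of them by at least 2-fold. Scaling by library size alone gave 161 positive and 380 negative. The fibroblast values of Adra1b rest on 0.357 CPM in serum-free medium and 1.18 CPM with phenylephrine, and those of Gpd1 on 2 and 11 counts, a ratio of 5.75 (95% counting interval 1.25 to 53.4).

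By list, cholesterol synthesis had the lowest camera adjusted p with all libraries and the preset correlation. Without both libraries that stand apart, actin and SRF targets had a lower one (camera adjusted p = 9.65e-10 against 2.93e-09). The difference for cholesterol synthesis was positive for 9 of 21 genes and negative for none (15 and 0 adjusted over the list alone), with a median of 0.74. Among these genes were Idi1 (1.11 ± 0.17), Sc5d (0.94 ± 0.15), Hsd17b7 (0.86 ± 0.13) and Cyp51 (0.81 ± 0.12). Camera adjusted p was 1.45e-10 (adjusted p = 0.746 with an estimated correlation). TEAD and YAP targets had 3 of 19 positive (8 adjusted over the list alone), Ankrd1 (0.87 ± 0.21), Tgfb2 (0.80 ± 0.13) and Lats2 (0.50 ± 0.095). For actin and SRF targets 1 of 23 was positive (4 adjusted over the list alone), Vcl (0.89 ± 0.16), and for myofibroblast genes 2 of 16 (7), Ddah1 and Fn1 (0.68 ± 0.16). Camera adjusted p for these lists was 1.38e-05, 2.71e-05 and 0.000469, and each had adjusted p = 0.746 with an estimated correlation. Interferon genes had 2 of 20 negative (4 adjusted over the list alone), Bst2 (-1.18 ± 0.19) and Ifi27 (-0.84 ± 0.11), with camera adjusted p = 0.00125, and leukocyte markers 0 of 17 (0), with 0.00164, both adjusted p = 0.746 with an estimated correlation. Immediate early genes split, with Nr4a1 (-1.29 ± 0.24) and Nr4a3 (-0.74 ± 0.18) negative and Ier3 (0.57 ± 0.077) and Egr2 (1.16 ± 0.28) positive, 2 and 2 of 20, also when adjusted over the list alone.

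Genes called in both cell types included shared and opposite changes. Of the genes tested, 29 rose with phenylephrine in both cell types, against 5.11 expected from independent lists (Fisher's exact test, one-sided p = 3.24e-14), among them Inha, Nr4a3, Slco2a1, Pde4b, Cpxm2, Bambi and Gata4. Slco2a1, Pde4b, Cpxm2 and Bambi fall outside the naming rule in cardiomyocytes, where they were chosen after their values were seen. In both cell types 2 fell, against 4.5 expected. Opposite changes also exceeded the expected numbers, with 19 genes that rose in cardiomyocytes and fell in fibroblasts, against 4.38, and 12 the other way, against 5.26. Both contrasts came from the same fit with a shared spread per gene, and genes are not independent. Overlap in either direction can thus exceed the expected numbers without a shared response, and the Fisher p-value does not measure one. The interaction passed for Pde4b (-2.00 ± 0.13, edgeR adjusted p = 9.51e-05), Slco2a1, Cpxm2 and Nr4a3, each of which rose more in fibroblasts, and did not for Inha (adjusted p = 0.212). Across the 13869 genes, which are not independent replicates, the log2 changes in the 2 cell types had a Pearson correlation of 0.01.

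The interaction calls also depended on single libraries. Leaving out 1 library at a time gave 71 genes without fibroblast phenylephrine replicate 1, 72 without its replicate 2, 142 and 473 without serum-free fibroblast replicate 1 and 2, 185 to 227 without any of the 4 cardiomyocyte libraries that do not stand apart, 823 without cardiomyocyte phenylephrine replicate 1 and 1290 without serum-free cardiomyocyte replicate 2. Without both of the last, 2657 genes were called. The number of lists called went from 6 to at most 12 when 1 library was left out and to 14 without both. The gained lists included smooth muscle and pericyte markers (positive, camera adjusted p = 8.43e-05), cell cycle genes (positive, 0.00219), the matrix (positive, 0.0227), hypertrophy (positive, 0.0185), Gq signalling (positive, 0.0185) and inflammation (negative, 0.0269), all without serum-free cardiomyocyte replicate 2. Without cardiomyocyte phenylephrine replicate 1, glycolysis (positive, 0.0246), epicardial (negative, 0.00631) and erythroid markers (negative, 0.0029) gained a call, and without its replicate 3 oxidative phosphorylation (negative, 0.0138) and fatty acid oxidation (negative, 0.0467). Mef2c, Spry4, Tnfrsf12a, Snap91, Sorbs2, Dact2, Cdkn1c, Pi16 (-2.40 ± 0.32), Ifi27 and Ier3 kept their calls in each of these settings, and every other gene named as different by the named-gene rule lost its call in at least 1.

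**Figure D3:**
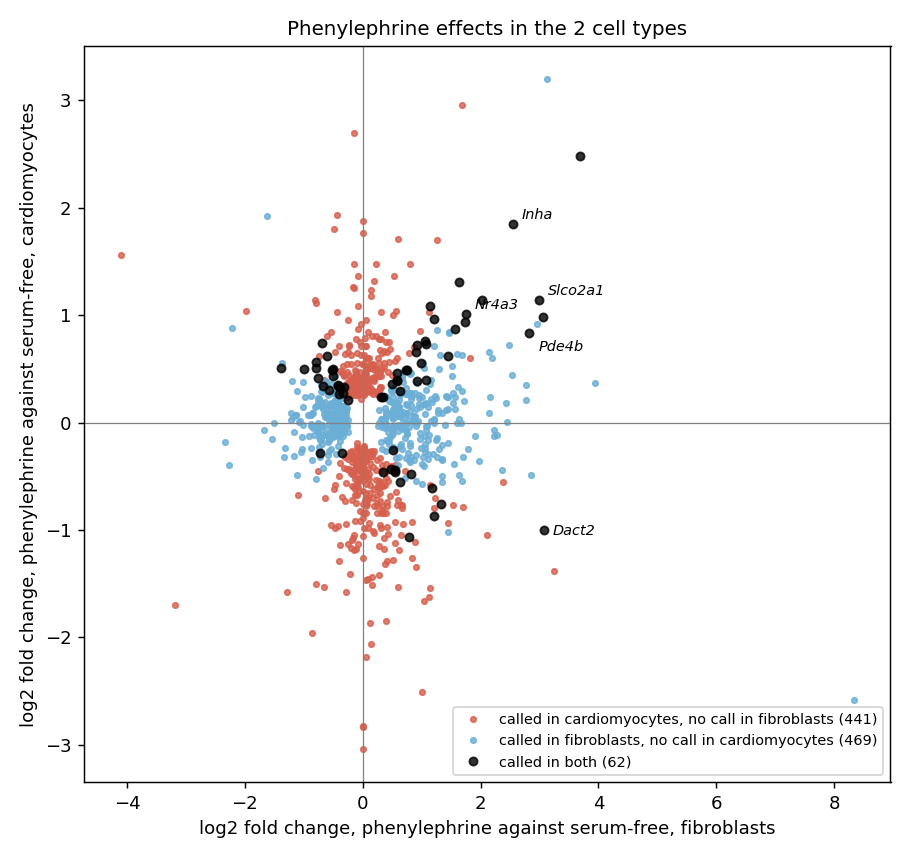
Log2 fold change with phenylephrine in fibroblasts (x axis) and in cardiomyocytes (y axis) for the 972 genes called in either cell type, coloured by where they were called. The 62 genes called in both include 29 that rose in both, such as Inha at 2.55 and 1.84, and genes on opposite sides, such as Dact2 at 3.07 and -1.

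The authors' deposited table holds its own differential expression results, from DESeq2. At an adjusted p below 0.05 it calls 792 genes for phenylephrine in cardiomyocytes, of which 495 are among the 503 called here, all in the same direction. For phenylephrine in fibroblasts the authors' deposited table calls 651, with 510 shared. For cell type it calls 8574 in serum-free medium and 8291 with phenylephrine, with 8489 and 8220 shared. Log2 fold changes in the authors' deposited table and here had a Pearson correlation across genes of 0.997, 0.984, 0.997 and 0.997 in that order.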

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

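The tests of carried-over fibroblasts, dilution, exchanged labels and treated cells in a serum-free library were chosen after the result was seen; the comparison of splits was chosen before.

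Phenylephrine had different effects in the cultures of the 2 cell types, by a test of the difference, for 45 named genes and 6 lists. Values are the log2 change in cardiomyocytes minus that in fibroblasts. More negative in cardiomyocytes were Dact2 (-4.07), Cdkn1c (-3.35), Gpd1 (-2.94), Dcn (-2.69), Adra1b (-2.49), Smoc2 (-2.48), Nppc (-2.43), Pi16 (-2.40), Cpxm2 (-2.07), Pde4b (-2.00), Slco2a1 (-1.85), Hopx (-1.70), Pde4d (-1.70), Nr4a1 (-1.29), Bst2 (-1.18), Ifi27 (-0.84), Nr4a3 (-0.74), Ptx3 (-0.61) and Tead2 (-0.56). More positive were the cholesterol synthesis genes Idi1 (1.11), Sc5d (0.94), Hsd17b7 (0.86), Cyp51 (0.81), Fdft1 (0.74) and Nsdhl (0.66), and the cytoskeletal, TEAD and matrix genes Vcl (0.89), Ankrd1 (0.87), Tgfb2 (0.80), Fn1 (0.68), Lats2 (0.50), Ddah1 (1.23) and Sorbs2 (1.58). The same held for Atcay (1.95), Fam174b (1.92), Snap91 (1.90), Rgs6 (1.6), Fras1 (1.58), Eno3 (1.39), Mef2c (1.36), Adprhl1 (1.31), Spry4 (1.17), Egr2 (1.16), Tnfrsf12a (0.87), Ier3 (0.57) and Skil (0.55). Median differences were 0.74 for cholesterol synthesis, 0.76 for myofibroblast genes, 0.41 for actin and SRF targets, 0.41 for TEAD and YAP targets, -0.38 for interferon genes and -0.83 for leukocyte markers; each had adjusted p = 0.746 with an estimated correlation. Cell type and passage cannot be told apart in these differences. The leukocyte list marks other cells in the cultures, so its difference need not be an effect in either cell type. In fibroblasts its mean log2 CPM was 0.54 and 0.57 with phenylephrine and -0.18 and 0.62 in serum-free medium. The fibroblast values of Gpd1 and Adra1b rest on the low levels given above.

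Cardiomyocyte phenylephrine replicate 1 and serum-free replicate 2 deviated from their group mates together: of 9025 genes, 7 were at least 2-fold higher in both, among them Col3a1, Col5a3 and Col11a1, where 0.0489 were expected, and 8 lower in both, among them Lcn2, Cxcl6 and Ccl2, where 0.0539 were expected. In 23 other genes found almost only in fibroblasts the excess was at the median 2.79% and 2.06% of the fibroblast level, and at most 6.06% and 4.74%. Of the 7 higher genes, 4, among them Col3a1 and Col5a3, are not so restricted. They would need fibroblasts like those sequenced to supply at least 12.8% and 15.7% of the RNA, up to 56.2% and 212%. The selection widened this gap: the 23 leave out genes higher in both libraries, and the 4 were picked for a 2-fold rise. All 26 genes found almost only in fibroblasts, not picked by their excess, had medians of 2.93% and 2.06%, with upper quartiles of 4% and 3.23%. Such an excess is too small for the 4, which argues against more such fibroblasts as their cause. The other 3 of the 7 higher genes, among them Col11a1 and Ptn, need 2.17% to 8.7% and 1.22% to 11.4%. With 3 genes, carried-over fibroblasts cannot be told apart here from a change in the cardiomyocytes. Fibroblasts in another state than those sequenced stay open. Dilution of cardiomyocyte RNA was argued against by sarcomere genes at log2 -0.09 and 0.19, where the lower genes had medians of -1.82 and -2.31. Exchanged labels would place phenylephrine replicate 1 nearer the other serum-free (0) than the other phenylephrine (1) libraries, but it lay at 0.74. The 95% interval of 0.71 to 0.76 came from resampling genes, which are not independent, and holds no spread between libraries. The position leans against exchanged labels but rests on a single library. Serum-free replicate 2 lay at 0.57 over 3486 genes but at 0.4 over the 88 of them that changed alike in fibroblasts, where phenylephrine replicate 1 lay at 0.94. In serum-free replicate 2 the positions of single genes were spread, with 17.1% of 140 genes near the serum-free end and 19.3% near the other, so treated cells in that library cannot be told apart from a difference in the state or preparation of the culture, which the labels do not give.

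For phenylephrine in cardiomyocytes 503 genes were called, and the highest other split of the 6 libraries called 9; the real split, 1 of 10, is among too few for a share under 0.05.

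The 29 genes that rose in both cell types, such as Inha and Nr4a3, could reflect fibroblasts carried over into the cardiomyocyte cultures. Their rise in cardiomyocytes was at the median 65.8% of that in fibroblasts (quartiles 47.7% and 158%). The highest carried-over share was 7.71%, and 28 of the 29 lay above it. That share came from 26 genes picked as almost fibroblast-only (a ratio of 16), which keeps it low. Col1a1, Postn and Tcf21 differed less between the cell types and would give a higher share. The share also takes carried-over cells to be like the passaged fibroblasts sequenced. For such fibroblasts the values argue against carry-over for the genes above the lower quartile of 47.7%. Genes below that quartile were not set against a share higher than 7.71%. Carried-over fibroblasts in another state, such as unpassaged ones, stay open. A response shared by both cell types stays open as a hypothesis.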

How the results depend on the processing

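Library size scaling, leaving out both libraries that stand apart, the surrogate variable and the crossed fibroblast block were chosen after seeing the data. Among settings of the genes named by the rule, the direction of a call reversed in 0 of 2251 and 2236 for cell type (serum-free and with phenylephrine), 2365 and 2028 for phenylephrine (cardiomyocytes and fibroblasts) and 2879 for the interaction. Calls were lost in 7, 6, 265, 154 and 173 of these. The settings include genes without a call in the main fit, which had none to lose. Among called genes alone the share of lost calls was therefore higher.

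A threshold of at least 2-fold lowers every count by construction, to 3972 and 3845 for cell type, 89 and 150 for phenylephrine in cardiomyocytes and fibroblasts, and 157 for the interaction. DESeq2 called 944 for phenylephrine in cardiomyocytes and 781 for the interaction. A fit of the compared groups alone called 91 in cardiomyocytes and 1306 in fibroblasts. The replicate block, which pairs libraries by number, called 195 and 225, and 198 for the interaction. Same-numbered deviations had r of -0.44, -0.33 and 0.11 in cardiomyocytes and -0.17 in fibroblasts over 2000 genes. These values cannot show whether the numbers pair the samples, and the labels do not say. In fibroblasts every pair must give the same value with or without its sign changed (-0.17 or 0.17). In cardiomyocytes both libraries that stand apart weigh on r, and they carry different numbers. The block with the fibroblast numbers crossed called 240 in fibroblasts and 190 for the interaction. The surrogate variable, which marked cardiomyocyte phenylephrine replicate 1, called 1083 in cardiomyocytes and 817 for the interaction, and leaving out both libraries that stand apart 3486 and 2657. For these differences the cause was not tested.

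Leaving out 1 library at a time gave 8056 to 9256 and 7446 to 9048 genes for cell type, 32 (without cardiomyocyte phenylephrine replicate 2) to 2371 (without serum-free replicate 2) in cardiomyocytes, 112 (without phenylephrine replicate 1) to 516 in fibroblasts, and 71 to 1290 for the interaction. Lists called numbered 2 (without phenylephrine replicate 2) to 5 in fibroblasts and 6 to 12 (without serum-free cardiomyocyte replicate 2) for the interaction, with 10 without cardiomyocyte phenylephrine replicate 3 and 14 without both libraries that stand apart. With an estimated correlation 0 lists were called in every contrast. Even the sarcomere list, with all 28 genes higher in serum-free cardiomyocytes, had camera adjusted p = 0.19 there. A missing call in that setting therefore does not show that a list is unshifted. With 2 libraries per fibroblast group, a lone library is assumed to vary like the others. Depth set the floor of 3 counts at 0.132 to 0.166 CPM in a library; Adra1a and Adra1d each had 3 counts over the serum-free fibroblast group.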

Other observations

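The CREB test described here was written before its genes' values were looked at; the values on individual odd-library genes were chosen after the result was seen.

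In the 2 cardiomyocyte libraries that stand apart, 8 genes were lower in both and 7 higher. Among those lower, Lcn2, which encodes the siderophore-binding lipocalin 2, was lower than in its group mates by log2 -2.26 in phenylephrine replicate 1 and -3.22 in serum-free replicate 2. The chemokine Cxcl6 had -1.95 and -3.36, the secreted phospholipase Pla2g2a -2.03 and -3.47, and Ccl2, a chemokine for monocytes, -1.13 and -1.55. Among those higher were Col3a1 at 1.11 and 1.03, Col5a3 at 1.34 and 1.68 and Ptn, a heparin-binding growth factor, at 1.21 and 1.29. These genes were chosen after their values were seen.

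Fibroblasts had few alpha1 receptor transcripts, Adra1a at 0.0759 CPM in serum-free medium and Adra1b at 0.357 CPM there and 1.18 CPM with phenylephrine, and the receptor list had no camera call there (adjusted p = 0.146, but 0.0326 without phenylephrine replicate 2 and 0.0464 without serum-free replicate 1, both higher), yet 286 genes rose with phenylephrine, and Pde4b and Nr4a1 were among them. A candidate explanation was activation of the cAMP and CREB pathway. The test was a list of 25 known CREB targets, of which 23 were measured. In fibroblasts camera with the preset correlation gave p = 0.677 (0.662 with an estimated correlation), and 2 genes rose, Pde4d (log2 1.34 ± 0.25, edgeR adjusted p = 0.0191) and Pde3b (0.64 ± 0.15, 0.0471), with 2 up and 1 down adjusted over the list alone. The list was not shifted in cardiomyocytes or in the interaction either, by the same test. Pde4d differed between the cell types by log2 -1.70 ± 0.3 (edgeR adjusted p = 0.0207). The list left out Pde4b, Nr4a1, Nr4a3 and Inha, which are also known CREB targets and rose in fibroblasts (log2 2.83 ± 0.11, 1.41 ± 0.19, 1.75 ± 0.14 and 2.55 ± 0.24), so its lack of a shift excludes nothing and the explanation stays open.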
